A study of Ginkgo biloba with 6 samples.

How the data were processed

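Transcript levels were measured by RNA sequencing of total RNA from Ginkgo biloba seedling leaves, in 3 control and 3 UV-B libraries. Per the labels' protocols, seedlings grew at 25 °C by day and 18 °C by night with 16 h of light and 8 h of dark, under fluorescent tubes giving photosynthetically active radiation of about 350 μmol per square metre and second. UV-B came from a system of 3 mercury-vapor lamps, RNA was extracted with a plant RNA kit and libraries followed standard Illumina procedures. The groups and replicate numbers were taken from the sample titles.

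The authors deposited 1 table of raw read counts, with 43190 loci as rows and 1 column per library. The values were whole numbers whose column totals differed, and they were not normalized. The submitters' processing notes name CASAVA 1.8, TopHat2 and HTSeq 0.9.1, with no role or order. The genome build, the annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Without them, counts of near-identical gene copies and of overlapping or antisense genes are uncertain. The table held 0 rows that name no gene, and each column name matched 1 sample title. No table pairing the identifiers with names, functions or coordinates was used here. For that reason 17 lists of match words written beforehand (flavonoid and phenylpropanoid enzymes, UV-B signalling, photosynthesis, DNA repair, markers of other material and others) were not applied, the checks of GC content and gene length were not run, and the named genes were limited to 4.

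All values were computed from the deposited counts with R 4.3.3. Of 29656 loci with at least 1 read (13534 had none), 23641 passed edgeR's filterByExpr and were tested, 22424 of them with a Gb identifier and 1217 with another prefix (non-Gb loci). They held over 99.9% of the counts of each library. Library totals were scaled by TMM factors, which ranged from 0.90 to 0.95 in control and from 1.05 to 1.15 in UV-B libraries. Groups were compared by the quasi-likelihood test of edgeR 4.0.16 (two-sided, group as the only term, Benjamini-Hochberg adjustment, threshold 0.05). The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic, and the 95% confidence interval from the t distribution with the fit's degrees of freedom. CPM of named genes, and log2 CPM in principal components and correlations between libraries, are TMM-scaled. Abundance classes and presence or absence used CPM of the total counts. Abundance classes were compared with camera and an estimated correlation in limma 3.58.1. Single values per library were compared by exact permutation tests.

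The rule for named genes was the 2 strongest rises and 2 strongest falls among genes past the threshold with at least a 2-fold change, a mean of at least 5 CPM and groups that did not overlap. This rule, the main test, the alternatives and the presence limit were fixed before the data were examined. The abundance classes were added afterwards. Alternatives were RLE, upper-quartile and no composition factors, no low-count filter, a minimum mean of 5 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, an adjusted p below 0.01, and glmTreat against a 2-fold change.

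The test was run on data simulated from the means, library sizes and dispersions of this comparison, with 200 changed genes among 23356 tested. It recovered 1 of 67 genes changed 1.5-fold (1.49%), 17 of 67 changed 2-fold (25.4%) and 50 of 66 changed 4-fold (75.8%), and called 5 unchanged genes. The changed genes had at least 1 CPM, and as many were raised as lowered. The adjusted threshold depends on how many genes change. These rates therefore need not hold for the real comparison, where 2067 genes were called. The depth was 37528794 to 47559213 counts per library. Reads carry no molecular identifiers, so floors based on counts cover counting error only. The intervals of fold changes come from the edgeR fit, which includes the spread between replicates. The labels give no sequencing date or batch.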

Results

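The series asked how leaf transcripts of Ginkgo biloba, a gymnosperm tree grown for its flavonoid-rich leaves, responded to ultraviolet-B (UV-B) light, a band of ultraviolet radiation present in sunlight. RNA sequencing libraries were made from seedling leaves of 2 groups with 3 replicates each. The UV-B group received a daily dose of 21.42 kJ/m2 for 14 days, and the control group grew for 14 days in white light from which UV-B was absent. The labels do not say whether the replicates came from separate plants, so the p-values measure the spread between these libraries, which may in part be technical. Read counts were given for 43190 loci, of which 41840 had gene identifiers with the prefix Gb and 1350 had other identifiers (non-Gb loci). Total counts ranged from 37528794 in control replicate 2 to 47559213 in UV-B replicate 1. The group means were 42831977 ± 4666829 (SD, n = 3) in control and 42514249 ± 4465989 (SD, n = 3) in UV-B leaves, a difference smaller than the spread between replicates (exact two-sided permutation test, p = 1, where the smallest p that 3 against 3 libraries allow is 0.1). A count was present for 26823 ± 309 loci (SD, n = 3) per control library and 27107 ± 536 loci (SD, n = 3) per UV-B library. The identifiers were not paired with gene names or functions, so the pathways of the study's title, flavonoid synthesis included, are not analysed here, and genes are described by abundance, by direction of change and by class of locus.

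UV-B and control leaves differed more between groups than within them. The first principal component of log2 CPM (counts scaled to a common library total, here with TMM factors) held 50.6% of the variance. It separated the groups, with control libraries between -71.3 and -49.2 and UV-B libraries between 55.2 and 66.0. The second component held 16.5% and did not separate them. Pearson correlations of log2 CPM across genes, which are not independent replicates, ranged from 0.96 to 0.97 between libraries of one group and from 0.92 to 0.95 between libraries of different groups. Replicates varied to a like degree in both groups, with a common biological coefficient of variation of 0.263 in control and 0.268 in UV-B leaves. No library was a copy of another, since the chi-square statistic of each pair within a group was 41.6 to 94.6 times its degrees of freedom.

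The main comparison asked which genes differed in transcript level between UV-B and control leaves. Of 23641 genes tested, 2067 (8.74%) changed, of which 664 rose and 1403 fell in UV-B leaves (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The risen genes had a median log2 fold change of 1.04 (2.05-fold) and the fallen genes one of -1.13 (2.19-fold). At least a 2-fold change was seen in 1154 of these genes, with 343 higher and 811 lower, and at least a 4-fold change in 479, with 150 higher and 329 lower. In each of the 2067 genes the 3 UV-B values lay wholly above or wholly below the 3 control values. Passing the test with 3 libraries per group largely requires this, so it adds no evidence for these genes. Of all 23641 tested genes, 8143 (34.4%) showed such a separation, which chance gives to 10% of genes. Under TMM scaling, the 95% confidence interval of the fold change lay within 2-fold in either direction for 14382 genes (60.8%). A change of that size was excluded for them at this scaling, depth and replicate number, gene by gene and without adjustment for multiple testing.

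The predominance of fallen genes depended on how libraries were scaled. With TMM factors, which set the median log2 fold change of all tested genes at 0.003, 32.1% of the changed genes were higher in UV-B leaves. Upper-quartile factors gave 939 higher and 1164 lower genes (44.7% higher). Scaling by library size alone moved the median of all genes to 0.23 and turned the balance, with 2895 higher and 976 lower genes (74.8% higher). Among genes of at least 2-fold change, the balance also turned, from 343 higher and 811 lower to 753 higher and 631 lower. All 664 genes that rose under TMM factors also rose with library size alone, 958 of the 1403 fallen genes also fell, and no gene was called in opposite directions. The number of calls also depended on single libraries. It was 1597 without control replicate 1, 715 without control replicate 2, 958 without control replicate 3, 1145 without UV-B replicate 1, 732 without UV-B replicate 2 and 939 without UV-B replicate 3 (edgeR, adjusted p below 0.05). Genes of at least 2-fold change numbered 576 without control replicate 2, 685 without control replicate 3, 598 without UV-B replicate 2 and 680 without UV-B replicate 3.

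**Figure D1:**
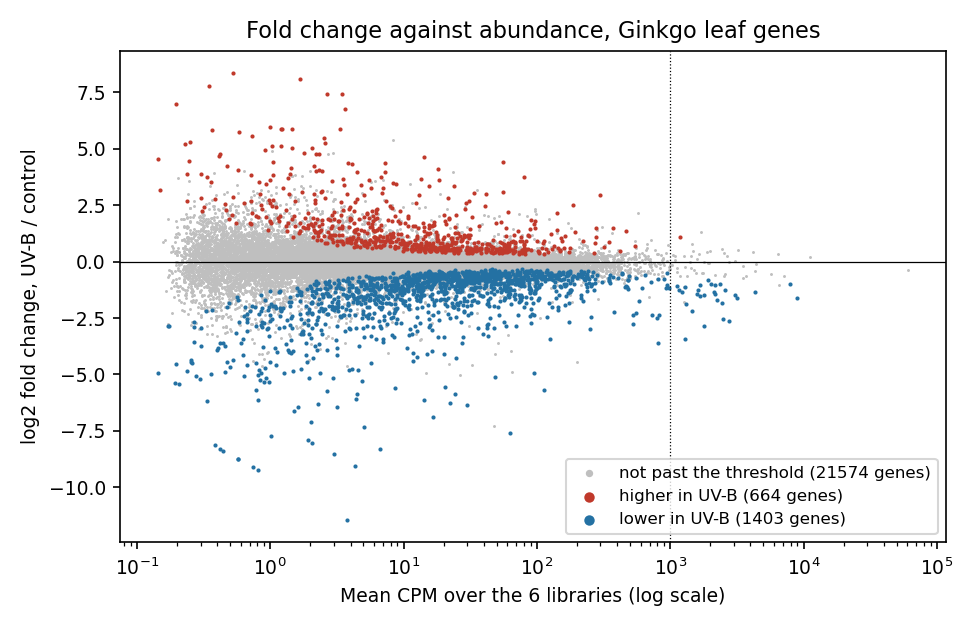
Each point is one of the 23641 tested genes, with its mean CPM over the 6 libraries on a log axis and its log2 fold change between UV-B and control leaves under TMM scaling on the vertical axis. Red points are the 664 genes that rose, blue points the 1403 that fell and grey points those not past an adjusted p of 0.05. Right of the dotted line at 1000 CPM, 29 genes fell and 1 rose; with library size alone, 29 fell and 10 rose.

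The most abundant transcripts of the leaf fell most often. Of the 80 genes with a mean of at least 1000 CPM over the 6 libraries, 29 (36.2%) fell and 1 (1.25%) rose, and 50 did not pass the test (edgeR, adjusted over all genes). Of the 29 fallen genes, 25 fell at least 2-fold and 5 at least 4-fold, with a median log2 fold change of -1.42 (2.67-fold) and a range from -0.84 to -3.44 (10.9-fold). Adjusted over the list alone, 38 of the 80 were lower and 6 higher. The direction held with library size alone, under which 29 of these genes were lower and 10 higher. Without UV-B replicate 2 the count of lower genes was 16 and without control replicate 2 it was 18. No abundant gene was called higher in edgeR without control replicate 3 or without UV-B replicate 1, 2 or 3 (5, 11, 4 and 5 genes at an unadjusted p below 0.05), and with all libraries DESeq2 called 7 and limma-voom 2 higher.

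These 80 genes took 29.0% ± 1.17 (SD, n = 3) of all counts in control and 23.3% ± 1.77 (SD, n = 3) in UV-B leaves, and the 3 control libraries all lay above the 3 UV-B libraries (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 allow). The single most abundant gene took 6.43% ± 1.08 (SD, n = 3) of control counts and 5.81% ± 0.46 (SD, n = 3) of UV-B counts, and its log2 fold change was -0.38 ± 0.26 (SE), with a 95% interval from -0.98 to 0.23 (edgeR, adjusted p = 0.386). The other 79 abundant genes took 22.5% ± 0.15 (SD, n = 3) and 17.4% ± 1.41 (SD, n = 3) of counts, respectively. The share in the 10 highest genes of each library was 13.6% ± 1.16 (SD, n = 3) in control and 11.6% ± 1.0 (SD, n = 3) in UV-B leaves (exact two-sided permutation test, p = 0.2).

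**Figure D2:**
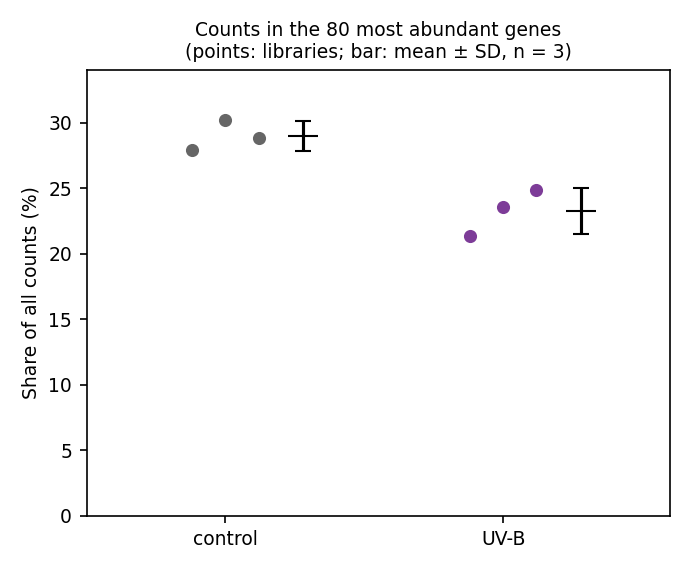
Points give the percentage of each library's counts that fell in the 80 genes with a mean of at least 1000 CPM, for 3 control and 3 UV-B libraries, and the bars give the mean ± SD. Control libraries sit between 27.9% and 30.2% and UV-B libraries between 21.3% and 24.8%.

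Under TMM scaling, the share of fallen genes increased stepwise with abundance, while the share of risen genes did not. Below 1 CPM, 87 of 3171 genes fell (2.74%) and 50 rose (1.58%). Between 1 and 5 CPM, 236 of 6021 genes fell (3.92%) and 163 rose (2.71%). Between 5 and 20 CPM, 391 of 6507 fell (6.01%) and 216 rose (3.32%). Between 20 and 100 CPM, 490 of 6236 fell (7.86%) and 196 rose (3.14%), and between 100 and 1000 CPM, 170 of 1626 fell (10.5%) and 38 rose (2.34%). With library size alone, by contrast, the share of risen genes increased too up to 100 CPM. It went from 111 of 3171 genes below 1 CPM to 1179 of 6236 between 20 and 100 CPM. More genes were then higher than lower in every class below 1000 CPM, and lower genes outnumbered higher ones only in the class of 1000 CPM or more. The median log2 fold change, relative to that of all genes, was 0.05 below 1 CPM, -0.08 between 100 and 1000 CPM and -0.55 at 1000 CPM or more, a difference that a scaling factor common to all genes of a library leaves as it is.

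A set test of the 6 abundance classes against the other tested genes called the class of 1000 CPM or more lower (camera with its preset correlation of 0.01, adjusted p = 1.25e-15) and the class of 100 to 1000 CPM lower (adjusted p = 0.0272). Neither call held when the correlation between genes was estimated from the libraries, with adjusted p = 0.239 and adjusted p = 0.555 respectively. The classes were defined after the data had been examined. Precision also differed between classes, since the median standard error of the log2 fold change was 0.55 below 1 CPM, 0.29 between 1 and 5 CPM, 0.17 between 5 and 20 CPM, 0.12 between 20 and 100 CPM, 0.13 between 100 and 1000 CPM and 0.21 at 1000 CPM or more.

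**Figure D3:**
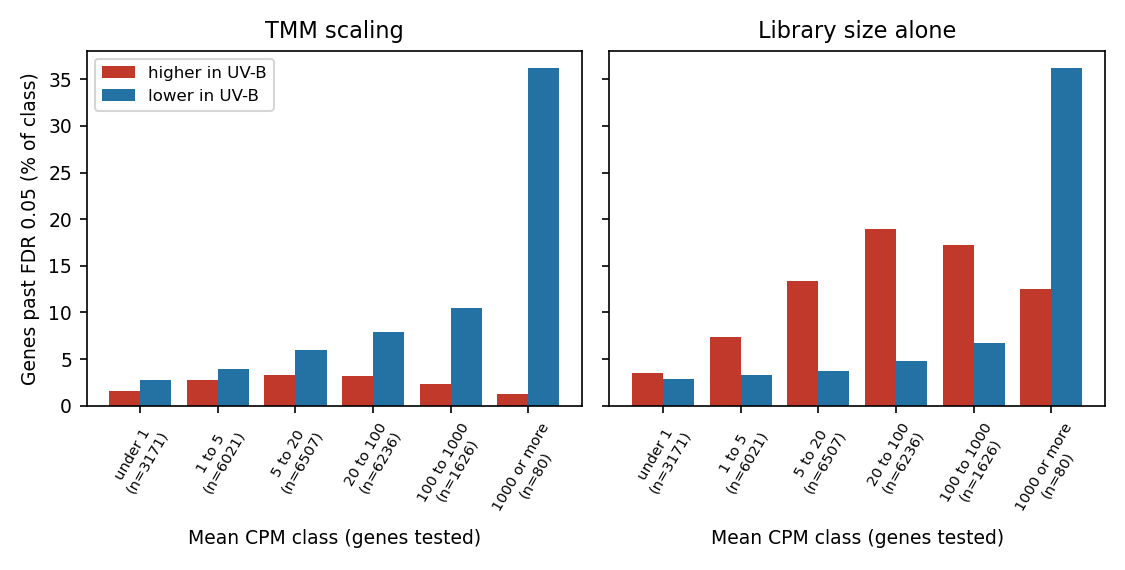
Bars give the percentage of tested genes in each class of mean CPM that were higher (red) or lower (blue) in UV-B leaves at an adjusted p below 0.05, with TMM scaling on the left and library size alone on the right. At 1000 CPM or more, 36.2% of the 80 genes were lower under TMM scaling and 29 of 80 were lower with library size alone, where in each other class more genes were higher than lower.

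Individual genes spanned changes from near absence to strong expression. Genes were ranked among those called (edgeR, adjusted p below 0.05) with at least 5 CPM, at least a 2-fold change and no overlap between the groups. These conditions were met by 158 higher and 512 lower genes. The strongest rises were those of Novel00971 and Gb_24809, and the strongest falls those of Gb_25966 and Gb_02312. Novel00971 rose from 0.971 ± 1.13 CPM (SD, n = 3) in control to 25.0 ± 5.57 CPM (SD, n = 3) in UV-B leaves, a log2 fold change of 4.65 ± 0.84 (SE; edgeR, adjusted p = 0.0222). Gb_24809 rose from 4.53 ± 4.50 to 96.6 ± 60.7 CPM (SD, n = 3 each), a log2 fold change of 4.40 ± 0.91 (SE; edgeR, adjusted p = 0.0319). Gb_02312 fell from 135.8 ± 61.3 to 0.73 ± 1.13 CPM (SD, n = 3 each), a log2 fold change of -7.61 ± 1.16 (SE; edgeR, adjusted p = 0.0145), and the 3 UV-B libraries held 1, 6 and 83 of its reads against 2956, 5181 and 7703 in control. Gb_25966 had 39, 968 and 583 reads in the control libraries and 0, 6 and 0 in the UV-B libraries, a fall from 14.6 ± 13.9 to 0.046 ± 0.080 CPM (SD, n = 3 each) with a fitted log2 fold change of -8.29 ± 1.62 (SE; edgeR, adjusted p = 0.0274). Its UV-B reads averaged less than the floor of 3 counts per library, so the fitted size depends on the prior count. The control mean was 221-fold that floor, a bound that covers counting error only and leaves out the spread between control libraries. The edgeR fit, which includes that spread, gave a 95% interval of the log2 fold change from -12.1 to -4.46.

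Among the 4 genes, the call of Gb_02312 alone held in each of 14 alternative fits, with adjusted p between 1.86e-05 and 0.0491 by edgeR, DESeq2 and limma-voom. Among the 6 edgeR fits that left out 1 library, the call of Novel00971 was lost without control replicate 1 (adjusted p = 0.0604) or without UV-B replicate 1, 2 or 3 (0.0589, 0.0575 and 0.0543). The call of Gb_24809 was lost in edgeR without each of the same libraries (adjusted p = 0.0859 without control replicate 1, and 0.0743, 0.0636 and 0.0613 without UV-B replicate 1, 2 or 3). Gb_25966 lost its call in limma-voom (adjusted p = 0.351) and in edgeR without control replicate 2 or 3 (0.0673 and 0.0594) or without UV-B replicate 1, 2 or 3 (0.0862, 0.0977 and 0.0858). The direction was kept in all 14 fits for each of the 4 genes. The rule that the groups did not overlap largely fixed this beforehand. Single libraries moved the size of the change. Without control replicate 3 the log2 fold change was 6.06 for Novel00971 and 5.49 for Gb_24809, and without UV-B replicate 1 it was 3.76 for Gb_24809. That of Gb_02312 was -6.97 without UV-B replicate 1 and -10.81 without UV-B replicate 3. The fitted value of Gb_25966 was -7.32 without control replicate 2 and -7.60 without UV-B replicate 1. Without UV-B replicate 2 no UV-B read of Gb_25966 was left, and the control mean was 227-fold the same floor. Limma-voom gave 5.76 for Novel00971 and -9.47 for Gb_02312. Coordinates and functions of these genes are not analysed here.

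Few transcripts were present in one group and absent from the other. Averaging at least 1 CPM in control leaves, 10 genes had no read in any UV-B library, and 2 genes with at least 1 CPM in UV-B leaves had none in any control library. Against a floor of 3 counts per library, the 10 genes were at least 15.0-fold to at least 477-fold lower in UV-B leaves, and the 2 genes at least 14.8-fold and at least 26.1-fold higher. Of the 10 genes, 6 had reads in all 3 control libraries and 5 passed the test of the main comparison, and of the 2 genes both had reads in all 3 UV-B libraries and 1 passed (edgeR, adjusted p below 0.05). Any other choice of 3 libraries left 0 to 4 genes without a read under the same minimum. These floors cover counting error only.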

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

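Each gene called in the main comparison kept its direction in each of the 14 alternative fits that tested it. The groups did not overlap in any of these genes, so fits to the same libraries could hardly reverse it. RLE factors, the fit without a low-count filter and limma-voom kept each count of calls within 1.5 times. The exception was 2 higher genes of at least 1000 CPM with limma-voom against 1. With library size alone 3871 genes passed (2895 higher), 753 were at least 2-fold higher, and 10 abundant genes were higher. DESeq2 called 4051 genes (1561 higher, 2490 lower), 1818 of them at least 2-fold (647 higher), and 7 abundant genes higher; the cause was not tested. An adjusted p below 0.01 left 275 genes (55 higher, 220 lower), and testing against a 2-fold change with glmTreat left 125 (31 higher, 94 lower), since both are stricter. A minimum of 5 CPM left 670 genes of at least 2-fold (165 higher, 505 lower), with fewer genes tested, and 2 abundant genes higher, as with upper-quartile factors. With the replicate block, which takes up degrees of freedom, edgeR called 930 genes (248 higher, 682 lower), 734 of at least 2-fold (198 and 536), and 18 abundant genes lower and 0 higher (5 higher at an unadjusted p below 0.05), and it ended the calls of Novel00971 (adjusted p = 0.0534) and Gb_24809 (adjusted p = 0.0529). Same-numbered libraries correlated in their deviations from the group means by 0.002, 0.13 and -0.05, and not every library correlated best with its own number, so the numbers were not taken as pairs. Leaving out 1 library gave 715 to 1597 genes (159 to 427 higher, 520 to 1170 lower), 576 to 1075 of at least 2-fold (129 to 275 higher, 424 to 800 lower), and 16 to 28 abundant genes lower with 0 to 1 higher (3 to 11 higher at an unadjusted p below 0.05 in edgeR), with fewer samples in each fit. Lowering the limit of the abundant class to 500 CPM, chosen after seeing the data, gave 47 lower and 2 higher genes. A minimum of 5 CPM left 2 genes without reads in UV-B and 0 in control libraries. The alternatives planned for lists of named functions were not run, because no names were used. Counting error alone would give a median standard error of 0.27 (log2) below 1 CPM, where the whole was 0.55, and 0.029 between 20 and 100 CPM, where it was 0.12.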

Other observations

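Loci without a Gb identifier (non-Gb loci), which made up 1217 of the tested genes, were called about as often as genes with a Gb identifier. Of the non-Gb loci 106 (8.71%) passed the edgeR test, 46 higher and 60 lower in UV-B leaves, against 1961 of 22424 Gb genes (8.75%), 618 higher and 1343 lower (odds ratio of being called 0.996, 95% interval 0.804 to 1.22, Fisher's exact test across genes, which are not independent, p = 1). Higher calls were a larger share in non-Gb loci (43.4%) than in Gb genes (31.5%) with TMM factors (odds ratio 1.67, Fisher's exact p = 0.0137, adjusted p = 0.0412 over 3 tests), but not with library size alone, where the odds ratio turned to 0.829 (p = 0.284). The non-Gb loci were also less abundant, with a median of 2.86 CPM against 9.39 CPM in Gb genes. In the class of 1 to 5 CPM as a whole 163 calls were higher and 236 lower. Calls made up 6.63% of that class and 9.33% of the class of 5 to 20 CPM. The like shares of calls therefore need not hold at like abundance, which was not compared. Non-Gb loci took 1.97% ± 0.14 (SD, n = 3) of control counts and 2.07% ± 0.17 (SD, n = 3) of UV-B counts. A further pattern concerned UV-B replicate 2. In it, 9 genes had no read although each had at least 1 CPM in all 5 other libraries, where the lowest of those levels would give at least 41.4 reads at its depth. Control replicate 2 had 1 such gene and the other 4 libraries 0.

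Of the tests that follow, the splits of the libraries for the 2 counts of all genes, the standard errors of the abundant genes, and the neighbour comparisons at 5 CPM and between single libraries were chosen after the result had been seen. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share below 0.05. The real split gave 2067 genes past the threshold, 1154 of them at least 2-fold, and 29 abundant genes in one direction, and the highest of the 9 other splits gave 0 in each case (edgeR), so 1 of 10 splits reached each of the 3 values. At an unadjusted p below 0.05 the other splits gave 364 to 1096 genes against 6505. Each of the other splits put control and UV-B libraries on the same side, so the group difference added to the spread within sides. That can lower the number of genes called, so the counts of 0 do not measure how many calls chance alone gives. DESeq2 and limma-voom were not run on the splits.

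Among the 80 most abundant genes 29 were called lower, 1 higher and 50 neither, and the set test of the class did not hold with an estimated correlation (camera, adjusted p = 0.239), so the pattern weighed here is the excess of lower calls. Greater power at high counts is argued against relative to genes of 100 to 1000 CPM. The median standard error of the log2 fold change was 0.209 in the 80 genes and 0.128 in those genes. It was higher by 0.0803 ± 0.009 (bootstrap SE over genes, which are treated as independent). That median was also lower between 5 and 20 CPM (0.17) and between 20 and 100 CPM (0.12). It was higher below 1 CPM (0.55) and between 1 and 5 CPM (0.29), so greater power stays open relative to genes below 5 CPM. Of the 50 genes not called, 30 lay below the median fold change of all genes. A single library as the whole cause of the lower fold changes is argued against too, because at least 35 of the 80 genes stayed more than 0.5 (log2) below that median when any 1 library was left out, against 42 with all libraries, although the calls themselves dropped from 29 to 16 without UV-B replicate 2 and to 18 without control replicate 2, with fewer samples in each fit. With library size alone 29 of the 80 genes were still lower. Those calls argue against the TMM scaling as the whole cause of the lower calls. The median log2 fold change of the 80 was then -0.33 ± 0.12 (bootstrap SE over genes). That SE treats the genes as independent and leaves out the spread between libraries, so it gives no test of the median. The scaling stays open as a part of the excess of lower over higher calls. With library size alone 2.90 of the genes were lower for each one that was higher, just short of the 3 set beforehand as the bound. The median of the class relative to all genes, -0.55 (log2), is left as it is by a factor common to all genes of a library. Transcript length, RNA quality and a changed make-up of leaf cells were not tested, and a response to UV-B is a further open explanation.

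Genes with consecutive identifier numbers tended to change together. Over 9844 such pairs of genes with at least 1 CPM, fold changes correlated with Spearman's rho of 0.145 (permutation p = 0.001, the smallest that 1000 shuffles can give), and the correlation was 0.061 at a distance of 2 numbers, 0.036 at 3 and 0.0001 at 5. Both genes were called in the same direction in 94 pairs (25 higher, 69 lower) against 50.6 on average and at most 73 in shuffled data, and in opposite directions in 33 pairs against 38.2. A shared abundance level is argued against, since shuffles among genes of like abundance reached at most 0.0349. One transcript split over 2 identifiers, or reads largely shared by near-identical neighbours, should keep the ratio of a pair steady between replicates. Pairs whose ratio varied more than that of the median random pair kept a correlation of 0.121 (shuffled at most 0.0528). With at least 5 CPM in both genes it was only 0.0741 (shuffled at most 0.0669). This argues against pairs of steady ratio as the whole cause. Neighbours that share only part of their reads can vary in ratio, so the comparison does not exclude them. The difference between 2 libraries of the same group gave 0.082 to 0.115 (6 pairs of libraries) and that between 2 libraries of different groups 0.104 to 0.136 (9 pairs), so a correlation was there without the UV-B contrast. Whether the numbers follow chromosomal position is not analysed here.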
